A study of Mus musculus with 6 samples.

How the data were processed

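The series holds 6 mouse femur RNA-seq libraries, 3 labelled OE and 3 labelled Ctrl, and groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, TopHat2, Cufflinks and DESeq were used with the mm10 build; their roles, versions and settings are not given in the sources used here. The deposited files hold FPKM per gene, per the file headers, with no counts. FPKM is scaled to each library's mapped fragments and to transcript length, so a few abundant genes lower the values of all others in a library. The strand setting and the treatment of reads shared between similar genes are not given in the sources used here. Each library lists 22824 rows. Of these, 21606 carry an Ensembl identifier, and 21172 of them matched a symbol in GENCODE M21 on GRCm38, the assembly that mm10 names; 1218 rows are unannotated transcripts numbered by the submitters. Some listed members of the gene lists were not analysed here because no row matched their symbol.

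Absolute depth is unknown. Values of weakly expressed genes move in steps whose size differs between libraries, and the ratios of these steps gave relative depths of 1.07, 1 and 1.12 for OE 1, 2 and 3, 1.14 for the library labelled Ctrl 1, and 1.02 and 1.18 for Ctrl 2 and Ctrl 3. FPKM totals ran from 596413 to 775942. An exact 0 can be a failed estimate: Col1a1 and Col1a2 are listed at 0 in 2 libraries where related genes are high. They are given per library only and are left out of list levels. They stay in the set tests, and removing them was an added alternative.

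The planned design named a count test if counts were held, and limma otherwise. Because the files hold FPKM, log2(FPKM + 1) was modelled with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), for the 12177 genes with at least 1 FPKM in at least 3 libraries. Differences are on the log2(FPKM + 1) scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 28 lists, of pathways and cell type markers, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 28 lists. Single values were compared with an exact two-sided permutation test. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

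The limma step was tested on simulated data made from the 12177 genes with 50 genes changed at each of 4 sizes. In the comparison of all 6 libraries it called 48% of genes changed by 1 in log2, 86% at 2, 98% at 3 and 98% at 4, with 8 unchanged genes called. In the comparison without the library labelled Ctrl 1 it called 42%, 74%, 98% and 94%, with 7 unchanged genes called. The noise was drawn separately for each gene and the changed genes were picked at random. These rates therefore do not hold for genes with a large spread shared between them, as in the bone genes, where Bglap differed by 3.40 (SE 1.33) and did not pass.

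Genes named in the text follow a rule fixed before the data were examined: Wnt7b; the 10 largest increases and 10 largest decreases among genes with a symbol that pass the threshold, average at least 1 FPKM in the higher group and do not overlap between groups; the 4 members of each list with the smallest p; and a fixed set of bone, marrow and metabolic genes. No gene met the second part with all 6 libraries at equal weight, so it was applied without the library labelled Ctrl 1. Axin2 is in the fixed set but was below the filter for testing, so only its values are given. S100a9, Col1a2, and the mitochondrial and Y-linked genes of the closing part were named after their values were seen. The other settings fixed at the same time were trimmed-mean scaling, scaling without marrow and muscle list genes, no filter and a filter of 5 FPKM. Fixed with them were limma without trend, a pseudocount of 0.1, the replicate number as a block, and leaving out each library. Scaling without marrow and muscle list genes left out the erythroid, neutrophil, B-cell and muscle lists, and no other list of marrow cells. Settings added after seeing the data were leaving out the libraries labelled Ctrl 1 and OE 3 together, array weights, trimmed-mean scaling without the library labelled Ctrl 1, and removal of genes listed at 0.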

Results

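RNA was measured by paired-end sequencing in femurs of C57BL/6 mice. In the OE group a Wnt7b allele at the R26 locus was switched on by Cre under Dmp1 regulatory sequence, which is active in osteocytes and mature osteoblasts. The Ctrl group held littermates with the Wnt7b allele and no Cre, and the labels describe all femurs as cleared of cartilage and marrow. Each group had 3 libraries. Nothing in the labels ties the libraries to separate animals, so the p-values measure the spread between these samples, which may in part be technical. The Y-linked genes of the closing part argue against repeats of the same RNA within OE, with Ddx3y at 3.42, 0.0183 and 14.8 FPKM in OE 1, 2 and 3. They also set the library labelled Ctrl 1, at 5.12, apart from Ctrl 2 and Ctrl 3, both listed at 0, but do not tell those 2 apart. Expression was given as FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, for 22824 genes. Absolute depth is therefore unknown, but the steps between low values put the relative depth of the libraries at 1 to 1.18. Between 11627 and 12258 genes reached 1 FPKM in a library. S100a8 and S100a9, which encode the calprotectin of neutrophils, together took 13.1%, 16.3% and 7.25% of all FPKM in OE 1, 2 and 3. They took 13.5% in the library labelled Ctrl 1, 13.1% in Ctrl 2 and 11.6% in Ctrl 3. Haemoglobin genes took 7.45% in OE 3 and 0.220% to 1.26% in the other libraries.

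Wnt7b, the gene the OE mice were built to express, was examined first in every library. It lies on chromosome 15, 85535437 to 85582473 (GRCm38, minus strand, ENSMUSG00000022382), and has 6 annotated transcripts with up to 4 exons. Wnt7b stood at 2.49 FPKM in OE 1, 0.661 in OE 2 and 0.295 in OE 3. The library labelled Ctrl 1 held 0.909 FPKM, more than OE 2 and OE 3, while Ctrl 2 held 0.00833 and Ctrl 3 was listed at 0. The group values were 1.15 ± 1.17 FPKM in OE and 0.306 ± 0.522 in Ctrl (SD, n = 3). The difference of 0.65 (SE 0.44) in log2(FPKM + 1) was within the replicate spread, with an exact two-sided permutation p = 0.3 where 3 against 3 libraries allow no p below 0.1. The limma adjusted p was 0.597, with Wnt7b kept in the model by hand because 1 library alone reached 1 FPKM. Wnt7b in the library labelled Ctrl 1 thus lay within the OE range. FPKM per gene does not tell transcripts of the R26 allele from those of the Wnt7b locus, so this puts the label in doubt without settling it. Every direction below that sets OE against Ctrl includes that library on the Ctrl side unless stated.

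**Figure D1:**
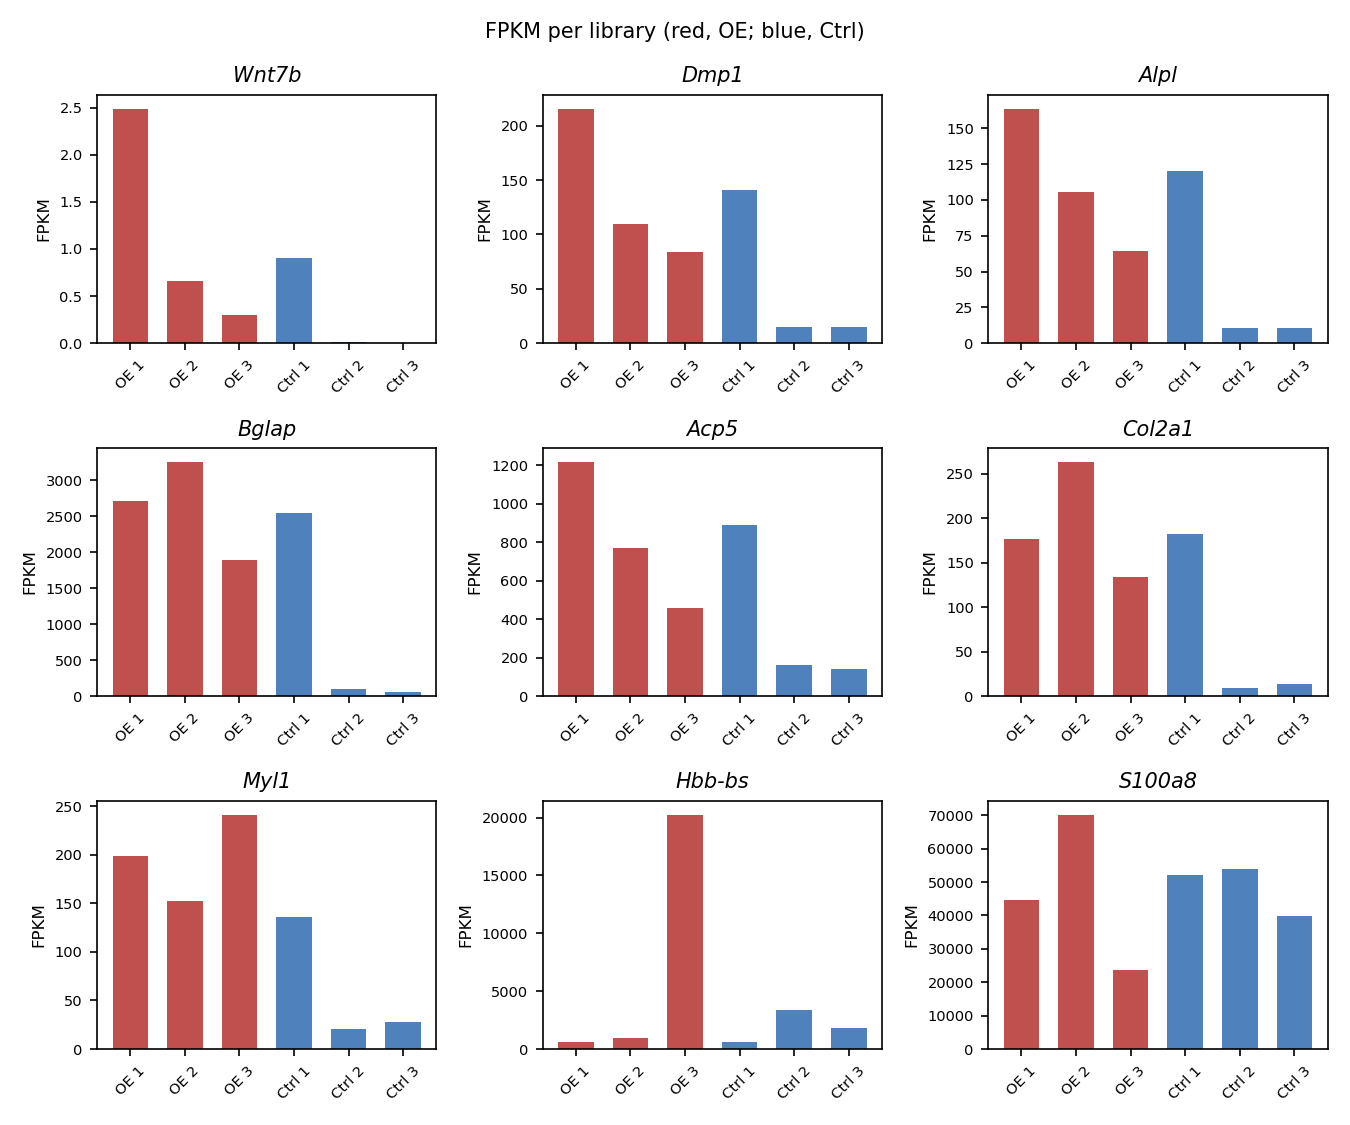
FPKM of 9 genes in each library, 1 bar per library, OE in red and Ctrl in blue, with a linear axis from 0 in each panel. Wnt7b, Dmp1, Alpl, Bglap, Acp5, Col2a1 and Myl1 were low in Ctrl 2 and Ctrl 3 and not in the library labelled Ctrl 1, and Hbb-bs was highest in OE 3.

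No gene among 12177 tested passed an adjusted p of 0.05 between OE and Ctrl by limma (smallest adjusted p = 0.554). At an unadjusted p under 0.05 there were 502 genes higher and 497 lower in OE, and 996 in all by limma without a trend. All OE values lay above all Ctrl values for 559 genes, or 4.59%, and below them for 1092, or 8.97%, where chance gives 5% each. Together these were 13.6% of the genes tested where chance gives 10%. The first principal component, with 55.0% of the variance, put OE 1, OE 2 and OE 3 at −38.9, −20.4 and −2.0, the library labelled Ctrl 1 at −25.5, and Ctrl 2 and Ctrl 3 at 45.9 and 40.8. The second, with 27.4%, set OE 3 apart at −50.4. Without the library labelled Ctrl 1 the limma count was 597 genes, which are described after the gene groups. Of the 28 gene lists fixed before the data were examined, camera, limma's set test, called 16 with a preset correlation of 0.01, 12 higher and 4 lower in OE. With the correlation estimated for each list, and with fry, 0 were called. No member of any list passed limma at an adjusted p of 0.05, over all genes or adjusted over the list alone, so the group sentences below give values and list tests. List levels are means of log2(FPKM + 1). Some lists share members, so lists that move alike are not separate evidence.

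**Figure D2:**
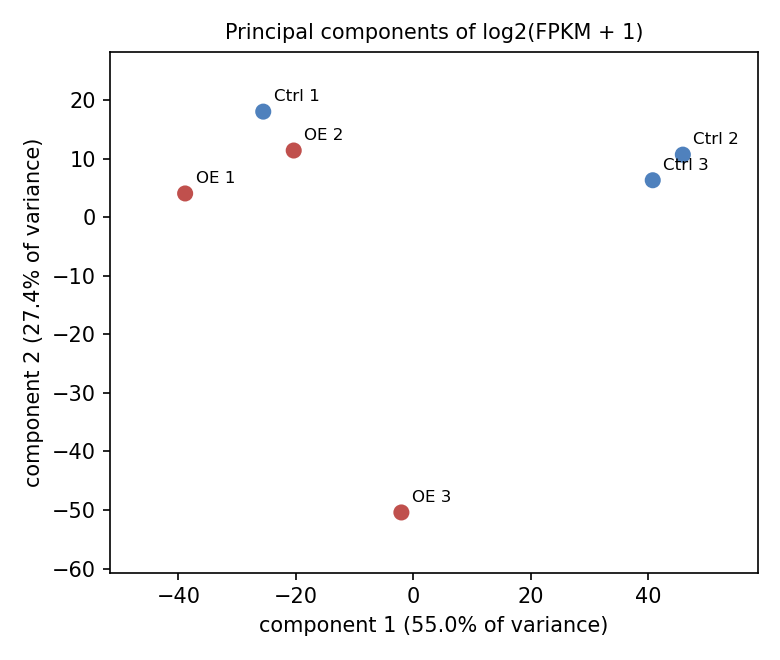
Position of the 6 libraries on the first 2 principal components of log2(FPKM + 1), 1 point per library, OE in red and Ctrl in blue. The library labelled Ctrl 1 lies at −25.5 on component 1, between OE 1 and OE 2, and OE 3 lies apart on component 2.

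Osteoblast genes were higher as a list in OE, and the difference came with low values in Ctrl 2 and Ctrl 3. All 24 members tested had a positive log2 difference, with a median of 1.98 (camera adjusted p = 1.56e-12, and adjusted p = 0.449 with an estimated correlation). The list level was 6.23, 5.71 and 5.37 in OE, 5.73 in the library labelled Ctrl 1, and 2.84 and 2.86 in Ctrl 2 and Ctrl 3. Bglap, which encodes osteocalcin, stood at 2711, 3254 and 1891 FPKM in OE, 2552 in the library labelled Ctrl 1, and 91.8 and 58.8 in Ctrl 2 and Ctrl 3. Alpl, the tissue-nonspecific alkaline phosphatase needed for mineral deposition, stood at 111 ± 49.8 FPKM in OE and 46.9 ± 63.3 in Ctrl (SD, n = 3). Sp7, a transcription factor required for osteoblast formation, stood at 27.2 ± 10.9 FPKM in OE and 11.0 ± 14.7 in Ctrl (SD, n = 3). In the library labelled Ctrl 1, Ctrl 2 and Ctrl 3, Alpl stood at 120, 10.3 and 10.4 FPKM and Sp7 at 28.0, 2.35 and 2.67. Runx2, which acts upstream of Sp7, differed less, at 14.1 ± 5.57 FPKM in OE and 9.07 ± 1.72 in Ctrl (SD, n = 3). Col1a1 and Col1a2, the type I collagen genes, were listed at 0 in OE 1 and in the library labelled Ctrl 1, where other osteoblast genes were high, so only their library values are given. Col1a1 stood at 3504 FPKM in OE 2, 3278 in OE 3, 179 in Ctrl 2 and 276 in Ctrl 3, and Col1a2 at 4029, 3236, 196 and 241.

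Osteocyte genes, from the cells in which the Dmp1 sequence is active, followed the same libraries. The list was higher in OE with a median of 1.02 over 18 members, 15 of them positive (camera adjusted p = 8.70e-06, and adjusted p = 0.449 with an estimated correlation). Dmp1, a matrix phosphoprotein of osteocytes, stood at 215, 109 and 83.8 FPKM in OE, 141 in the library labelled Ctrl 1, and 14.6 and 15.2 in Ctrl 2 and Ctrl 3. Phex, an endopeptidase that limits phosphate loss, stood at 23.6 ± 8.89 FPKM in OE and 6.78 ± 9.55 in Ctrl (SD, n = 3). Sost, which encodes the Wnt inhibitor sclerostin, stood at 162, 38.7 and 23.1 FPKM in OE, 97.7 in the library labelled Ctrl 1, and 11.7 and 15.2 in Ctrl 2 and Ctrl 3. The mineralization list had a median of 1.24 over 15 members (camera adjusted p = 7.64e-06, and adjusted p = 0.449 with an estimated correlation), with Ibsp, bone sialoprotein, at 411 ± 131 FPKM in OE and 164 ± 147 in Ctrl (SD, n = 3). The collagen processing list had a median of 1.23 over 26 members, 24 of them positive (camera adjusted p = 9.26e-09, and adjusted p = 0.449 with an estimated correlation). Lox, which crosslinks collagen, stood at 64.0 ± 38.4 FPKM in OE and 17.3 ± 22.5 in Ctrl (SD, n = 3), and Plod2, which hydroxylates its lysines, at 48.9 ± 14.9 FPKM in OE and 18.3 ± 24.5 in Ctrl (SD, n = 3). In the 18 osteocyte, 15 mineralization and 26 collagen processing members, the library labelled Ctrl 1 lay at or above the lowest OE library in 17, 13 and 24. Without it the mean difference moved from 1.01 to 1.56 for osteocyte and from 1.16 to 1.79 for collagen processing genes.

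Targets and antagonists of Wnt signalling were also higher as lists. Among 14 targets tested 12 were positive, with a median of 0.98 (camera adjusted p = 3.46e-06, and adjusted p = 0.449 with an estimated correlation). The level of the targets was 3.88, 3.40 and 3.36 in OE, 3.43 in the library labelled Ctrl 1, and 2.04 and 2.13 in Ctrl 2 and Ctrl 3. The library labelled Ctrl 1 lay at or above the lowest OE library in 9 of the 14, and 4 had all OE values above all Ctrl values. Ccnd1, which encodes cyclin D1 and is among these 4, stood at 7.60 ± 1.05 FPKM in OE and 3.75 ± 1.55 in Ctrl (SD, n = 3). Ccn4 stood at 23.8 ± 10.9 FPKM in OE and 7.18 ± 9.17 in Ctrl (SD, n = 3) and Tnfrsf19 at 14.2 ± 3.15 FPKM in OE and 5.30 ± 4.80 in Ctrl (SD, n = 3). Lef1, a transcription factor of the pathway, stood at 8.90 FPKM in OE 3 and between 0.348 and 1.81 in the other libraries. In OE 3, 13 of 14 B-cell list genes were also highest, so this value does not by itself speak for Wnt signalling. Axin2, a feedback target, did not reach the filter for testing and stood at 1.10, 0.907 and 1.05 FPKM in OE and 0.822, 0.880 and 0.810 in Ctrl, the library labelled Ctrl 1 first. All 8 antagonists were positive, with a mean of 1.10 (camera adjusted p = 1.00e-04, and adjusted p = 0.449 with an estimated correlation). Their level was 4.03, 3.32 and 2.79 in OE, 3.62 in the library labelled Ctrl 1, and 1.61 and 1.60 in Ctrl 2 and Ctrl 3, and the library labelled Ctrl 1 lay at or above the lowest OE library in 7 of the 8. Wif1 stood at 48.0 ± 17.4 FPKM in OE and 19.5 ± 23.7 in Ctrl (SD, n = 3) and Dkk1 at 29.8, 12.6 and 3.47 FPKM in OE, 19.0 in the library labelled Ctrl 1, and 1.18 and 0.932 in Ctrl 2 and Ctrl 3. The ligands and receptors other than Wnt7b had a median of 0.40 over 14 members (camera adjusted p = 8.78e-05, and adjusted p = 0.449 with an estimated correlation), with the receptor gene Fzd5 at 3.20 ± 0.909 FPKM in OE and 1.66 ± 0.447 in Ctrl (SD, n = 3). Without the library labelled Ctrl 1 the mean of the antagonists moved from 1.10 to 1.78. For ligands and receptors the mean moved from 0.36 to 0.19 without OE 1, and the call ended with a filter of 5 FPKM.

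Osteoclast genes were higher in OE as a list. The median was 0.20 over 19 members, 11 of them positive (camera adjusted p = 0.0246, and adjusted p = 0.583 with an estimated correlation). The level was 5.57, 5.23 and 5.09 in OE, 5.37 in the library labelled Ctrl 1, and 4.68 and 4.67 in Ctrl 2 and Ctrl 3. In 17 of the 19 members the library labelled Ctrl 1 lay at or above the lowest OE library. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, stood at 1216, 771 and 460.3 FPKM in OE, 888 in the library labelled Ctrl 1, and 161 and 143 in Ctrl 2 and Ctrl 3. Ctsk, the protease that degrades bone collagen, stood at 1255, 828 and 416 FPKM in OE. It stood at 1095 in the library labelled Ctrl 1, and at 137 and 104 in Ctrl 2 and Ctrl 3. The secreted regulators of osteoclast formation gave no call (camera adjusted p = 0.0772, and adjusted p = 0.449 with an estimated correlation). Tnfsf11, which encodes the osteoclast inducer RANKL, stood at 4.10 ± 0.293 FPKM in OE and 2.71 ± 1.02 in Ctrl (SD, n = 3). Tnfrsf11b, its decoy receptor, stood at 3.17 ± 0.637 FPKM in OE and 1.84 ± 1.43 in Ctrl (SD, n = 3). In the library labelled Ctrl 1, Ctrl 2 and Ctrl 3, Tnfsf11 stood at 3.89, 2.05 and 2.20 FPKM and Tnfrsf11b at 3.48, 1.13 and 0.899. The call on the osteoclast list ended when OE 1, Ctrl 2 or Ctrl 3 was left out, with a filter of 5 FPKM, and with scaling without marrow and muscle list genes, and the mean moved from 0.39 to 0.25 without OE 1 and 0.62 without the library labelled Ctrl 1. The regulators were called higher at the preset correlation with no filter or without the library labelled Ctrl 1, but in no setting with an estimated correlation (adjusted p = 0.343 at the lowest).

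Cartilage, skeletal muscle and fibrous tissue genes moved with the bone genes. The cartilage list had a median of 1.76 over 20 members (camera adjusted p = 3.28e-09, and adjusted p = 0.449 with an estimated correlation), and its level was 3.78, 4.05 and 3.34 in OE, 3.88 in the library labelled Ctrl 1, and 1.12 and 1.19 in Ctrl 2 and Ctrl 3. Col2a1, the main cartilage collagen, stood at 177, 263 and 134 FPKM in OE, 183 in the library labelled Ctrl 1, and 8.82 and 13.8 in Ctrl 2 and Ctrl 3. All 17 muscle genes were positive, with a median of 1.44 (camera adjusted p = 3.82e-11, and adjusted p = 0.449 with an estimated correlation). In 16 of the 17 both Ctrl 2 and Ctrl 3 lay below each of the other 4 libraries. Myl1, a myosin light chain, stood at 199, 153 and 241 FPKM in OE, 136 in the library labelled Ctrl 1, and 20.6 and 27.9 in Ctrl 2 and Ctrl 3, and Mb, myoglobin, at 71.3 ± 17.1 FPKM in OE and 23.0 ± 16.3 in Ctrl (SD, n = 3). The periosteum and tendon list had a median of 0.69 over 14 members (camera adjusted p = 0.00111, and adjusted p = 0.449 with an estimated correlation), with Postn, periostin, at 50.5 ± 20.7 FPKM in OE and 21.2 ± 20.6 in Ctrl (SD, n = 3) and Aspn, asporin, at 11.4 ± 3.17 FPKM in OE and 4.46 ± 2.13 in Ctrl (SD, n = 3). Without the library labelled Ctrl 1 the mean moved from 1.66 to 2.57 for cartilage and from 0.61 to 0.96 for periosteum and tendon, and without Ctrl 2 from 1.37 to 0.91 for muscle.

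**Figure D3:**
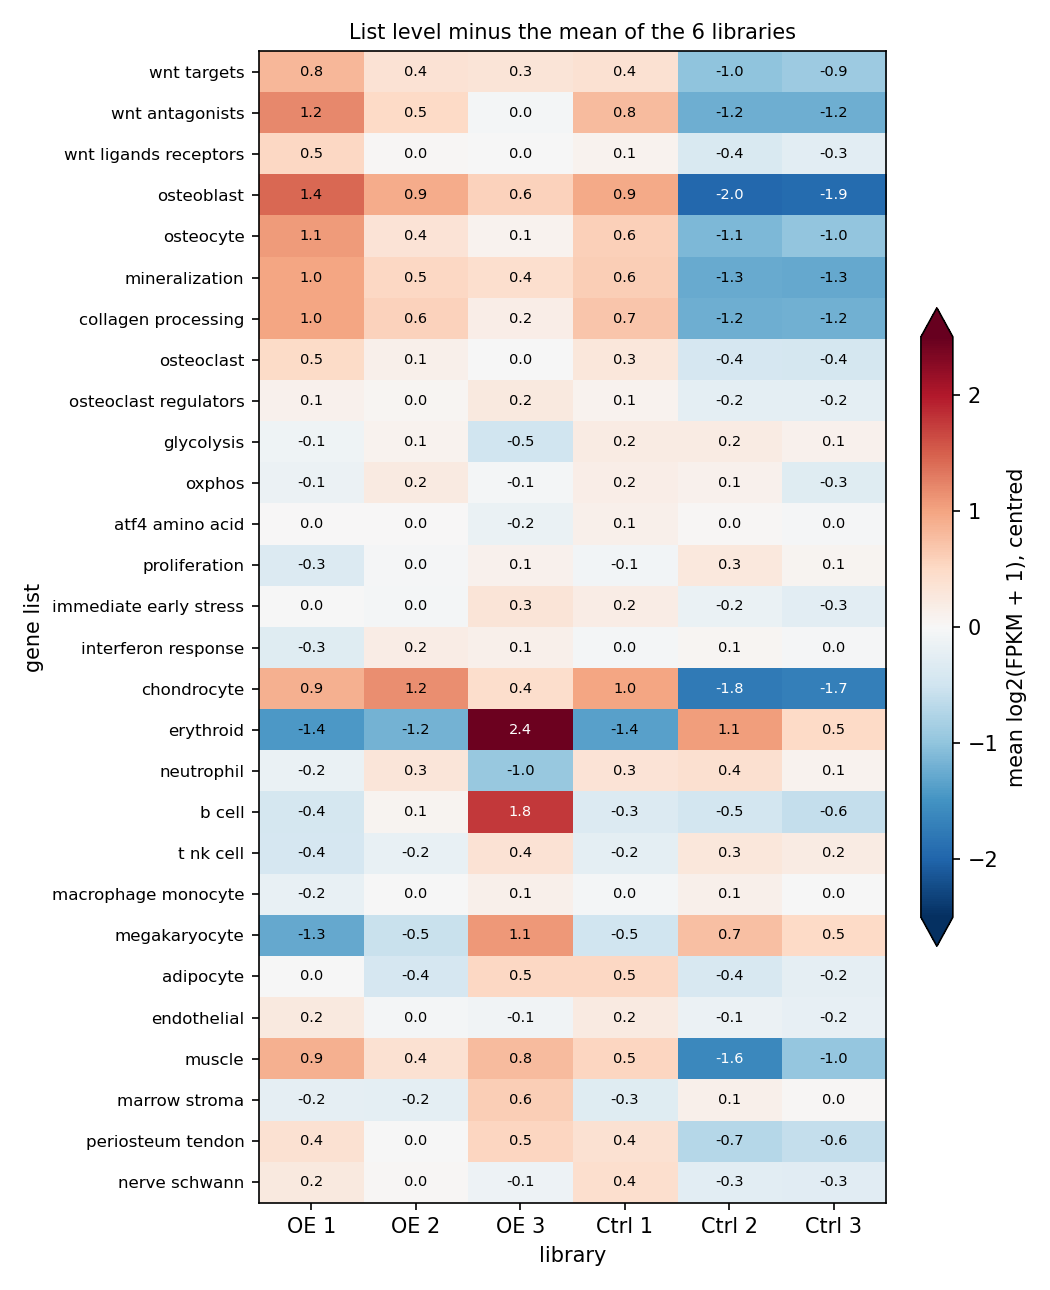
Level of each of the 28 gene lists in each library, as the mean of log2(FPKM + 1) over its members minus the mean of the 6 libraries, red above and blue below. The osteoblast, cartilage and muscle lists were below the mean in Ctrl 2 and Ctrl 3 and above it in the library labelled Ctrl 1, and the erythroid list was highest in OE 3.

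Neutrophil genes were abundant in every library, and OE 3 stood apart in erythroid and B-cell genes. The neutrophil list was lower in OE, with a median of -0.61 and all 20 members negative (camera adjusted p = 7.09e-06, and adjusted p = 0.525 with an estimated correlation). Its level was 10.39, 10.84 and 9.60 in OE, 10.89 in the library labelled Ctrl 1, and 10.94 and 10.64 in Ctrl 2 and Ctrl 3, so OE 2 lay above Ctrl 3. The mean moved from -0.55 to -0.21 without OE 3 and -0.83 without OE 2, and the call ended without the libraries labelled Ctrl 1 and OE 3 together. Mpo, the myeloperoxidase of neutrophil granules, stood at 2113 ± 798 FPKM in OE and 3640.1 ± 280.1 in Ctrl (SD, n = 3). The B-cell list was higher in OE, with a median of 0.82 over 14 members (camera adjusted p = 2.07e-04, and adjusted p = 0.525 with an estimated correlation), and 13 of the 14 were highest in OE 3. Igll1, a part of the pre-B-cell receptor, stood at 5.18, 11.5 and 91.1 FPKM in OE, 6.37 in the library labelled Ctrl 1, and 1.59 and 1.24 in Ctrl 2 and Ctrl 3. The erythroid list was not called (camera adjusted p = 0.996, and adjusted p = 0.999 with an estimated correlation), and all 19 members were highest in OE 3. Hbb-bs, a beta globin gene with a near-identical copy that makes its value uncertain, stood at 571, 969.5 and 20218 FPKM in OE, 577 in the library labelled Ctrl 1, and 3416 and 1818 in Ctrl 2 and Ctrl 3. Megakaryocyte genes were not called (camera adjusted p = 0.0747, and adjusted p = 0.811 with an estimated correlation), and 11 of 12 were highest in OE 3. Without OE 3 the mean of the B-cell list moved from 0.93 to 0.28 and its call ended, and the erythroid and megakaryocyte lists were called lower at the preset correlation. The same held with array weights, where the B-cell mean was 0.54, and without the libraries labelled Ctrl 1 and OE 3, where it was 0.34. The megakaryocyte list was also called lower without the library labelled Ctrl 1, with the replicate number as a block, and with either scaling. Neither list was called in any setting with an estimated correlation (adjusted p = 0.387 at the lowest for both).

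Other cell types gave no call with all 6 libraries at equal weight. The adjusted p of camera was 0.417 for T and NK cells, 0.937 for monocytes and macrophages, 0.236 for marrow stroma, 0.863 for adipocytes, 0.241 for endothelium and 0.919 for Schwann cells. Adipoq, the adipocyte hormone gene, stood at 10.1, 8.30 and 48.2 FPKM in OE, 14.4 in the library labelled Ctrl 1, and 8.86 and 7.95 in Ctrl 2 and Ctrl 3. Emcn, an endothelial sialomucin, stood at 19.4, 15.6 and 6.58 FPKM in OE, 17.0 in the library labelled Ctrl 1, and 5.69 and 4.75 in Ctrl 2 and Ctrl 3. Cebpa, a transcription factor of adipocytes that is also active in granulocytes, stood at 39.7 ± 3.79 FPKM in OE and 61.3 ± 7.57 in Ctrl (SD, n = 3), with all OE values below all Ctrl values. Single omissions changed 4 of these lists: T and NK cells and adipocytes were called lower without OE 3, endothelium higher without the library labelled Ctrl 1, and marrow stroma higher without OE 1 or OE 2. In settings added after seeing the data, T and NK cells were also called lower and endothelium higher. The camera adjusted p was 0.0270 and 0.0152 with array weights, and 2.42e-04 and 0.0213 without the libraries labelled Ctrl 1 and OE 3. It was 0.0491 and 0.0442 with trimmed-mean scaling without the library labelled Ctrl 1. With an estimated correlation none of the 4 was called in any setting, the lowest adjusted p being 0.387 for T and NK cells, 0.516 for adipocytes, 0.524 for endothelium and 0.387 for stroma.

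Glycolysis genes were lower in OE as a list. The median was -0.43 over 21 members, 2 of them positive (camera adjusted p = 8.78e-05, and adjusted p = 0.449 with an estimated correlation). The level was 6.55, 6.75 and 6.18 in OE, 6.87 in the library labelled Ctrl 1, and 6.87 and 6.78 in Ctrl 2 and Ctrl 3, and without OE 3 the mean moved from -0.35 to -0.19. OE 3 and OE 1 were lowest, and Ctrl 2 and the library labelled Ctrl 1 highest, as in the neutrophil list. Unlike in that list, every Ctrl level, with the library labelled Ctrl 1 included, lay above every OE level. All OE values lay below all Ctrl values in 8 of the 21 members, against 3 of 20 neutrophil genes. Hk1, a hexokinase, stood at 48.8 ± 5.08 FPKM in OE and 66.3 ± 7.79 in Ctrl (SD, n = 3), and Eno1, enolase, at 420.0 ± 135 FPKM in OE and 684 ± 74.7 in Ctrl (SD, n = 3). Pfkm, the muscle form of phosphofructokinase, went the other way at 22.4 ± 5.56 FPKM in OE and 13.8 ± 5.40 in Ctrl (SD, n = 3). Slc2a1, a glucose transporter, stood at 16.1 ± 4.57 FPKM in OE and 21.6 ± 1.82 in Ctrl (SD, n = 3). Dividing-cell genes were lower, with a median of -0.19 over 26 members (camera adjusted p = 0.00898, and adjusted p = 0.801 with an estimated correlation), and Cdc20, an activator of the anaphase-promoting complex, stood at 53.4 ± 7.20 FPKM in OE and 74.6 ± 8.33 in Ctrl (SD, n = 3). Targets of ATF4 and genes of amino acid supply were lower, with a median of -0.20 over 21 members (camera adjusted p = 0.0435, and adjusted p = 0.449 with an estimated correlation). Shmt2, of serine metabolism, stood at 29.2 ± 4.57 FPKM in OE and 44.8 ± 7.57 in Ctrl (SD, n = 3) and Asns, asparagine synthetase, at 29.5 ± 8.05 FPKM in OE and 46.2 ± 7.59 in Ctrl (SD, n = 3). The ATF4 call ended without OE 2, OE 3, the library labelled Ctrl 1 or Ctrl 3 and under the replicate block, the dividing-cell call ended without OE 1 or Ctrl 2, and both ended with a filter of 5 FPKM. The ATF4 mean of -0.094 moved to -0.037 without OE 3, -0.049 without the library labelled Ctrl 1, -0.049 with trimmed-mean scaling and -0.0085 with scaling without marrow and muscle list genes. The dividing-cell mean of -0.17 moved to -0.042 without OE 1, -0.27 without OE 3, -0.081 without Ctrl 2 and -0.081 with scaling without marrow and muscle list genes. The camera adjusted p was 0.695 for nuclear-encoded respiratory chain genes, 0.486 for immediate-early and heat-shock genes and 0.933 for interferon-stimulated genes. Interferon-stimulated genes were called higher without OE 1, and respiratory chain genes lower without Ctrl 3, but in no setting with an estimated correlation, where the lowest adjusted p was 0.535 and 0.817.

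Leaving out the library labelled Ctrl 1, whose Wnt7b level lay within the OE range, set the 3 OE libraries against Ctrl 2 and Ctrl 3. This setting was among the planned leave-outs, and its fuller account was chosen after the Wnt7b values were seen. The library left out is also the 1 Ctrl library that lay with OE in bone genes (osteoblast level 5.73 against 2.84 and 2.86). Its omission widens these differences, from a median of 1.98 to 2.78 over the 24 osteoblast genes. The mean moved from 2.02 to 2.68. Both means include Col1a1 and Col1a2 and are affected by their listing at 0 in OE 1 and the library labelled Ctrl 1. The calls below depend on the omission of that library. Limma then called 597 genes, 518 higher and 79 lower, of which 491 and 69 differed by at least 1 in log2. Camera called 18 lists, 0 with an estimated correlation (smallest adjusted p = 0.343), and fry called 5. Of 24 osteoblast genes 20 rose, as did 17 of 26 collagen processing, 13 of 20 cartilage, 11 of 17 muscle, 8 of 18 osteocyte, 7 of 15 mineralization and 6 of 14 Wnt target genes. Adjusted over the list alone, the counts were 20, 20, 18, 16, 13, 11 and 9. The counts overlap, since Smpd3, Ibsp and Phex of the mineralization list are also in the osteoblast or osteocyte list. The genes counted are low in both remaining Ctrl libraries, and the blood-cell lists differ between libraries as given above.

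Of the 518 higher and 79 lower genes called by limma without the library labelled Ctrl 1, 506 and 24 met the rule for naming, which also asks for a symbol, a mean of at least 1 FPKM in the higher group and OE values on 1 side of Ctrl 2 and Ctrl 3. The largest rise was in Col10a1, the collagen of hypertrophic cartilage (chromosome 10, 34389981 to 34397085, GRCm38), by 6.20 in log2(FPKM + 1) (SE 0.30, limma adjusted p = 0.00156). Bglap (chromosome 3, 88383501 to 88384464) rose by 5.10 (SE 0.35, limma adjusted p = 0.00289). Its neighbour Bglap2, a near-identical copy, rose by 4.78, and reads shared by the pair make both values uncertain. Sparc, osteonectin, rose by 4.06 (SE 0.37, limma adjusted p = 0.00462). The other genes among the 10 largest rises were Gm10709 at 5.48, Col11a1 at 4.54, Cpz at 4.06, Serpinf1 at 4.05, Cthrc1 at 4.04 and Col5a2 at 4.03. In the library labelled Ctrl 1, Col10a1 stood at 64.1 FPKM and Col11a1 at 97.0, against 0.406 and 3.94 in Ctrl 2.

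Igkv4-62, Jchain, Iglc2, Cpa3 and Fcer1a were among the 24 lower genes that met this rule. Igkv4-62, a kappa chain variable segment of a family with near-identical copies, changed by -3.11 (SE 0.16, limma adjusted p = 0.00156). Jchain, which joins secreted antibodies, changed by -1.87 and Iglc2, a lambda chain constant region, by -1.86. Jchain stood at 81.5, 73.4 and 76.2 FPKM in OE, 78.3 in the library labelled Ctrl 1, and 384 and 208 in Ctrl 2 and Ctrl 3. Cpa3, a mast-cell protease, changed by -1.34, and Fcer1a, a chain of the IgE receptor, by -1.28. The others of the 10 largest decreases were Dpep2 at -1.60, Serpina3n at -1.57, Igkv4-71 at -1.55, Serpina3b at -1.49 and Gm21188 at -1.48. Without OE 3 as well, an alternative added after the data were seen, limma called 1388 genes, among them all 597.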

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

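The additions made after seeing the data were the joint omission of the libraries labelled Ctrl 1 and OE 3, array weights, trimmed-mean scaling without the library labelled Ctrl 1, and removal of genes listed at 0. The direction of Wnt7b held under each alternative, from 0.24 to 0.96 over single omissions and 2.05 with a pseudocount of 0.1, and it passed none. The limma count of 0 genes held under trimmed-mean scaling, scaling without marrow and muscle list genes (library medians moved by −0.15 to 0.16 in log2), both other filters, no trend, a pseudocount of 0.1, and removal of genes listed at 0. Single omissions gave 0 to 597 genes changed, 0 to 518 higher, 0 to 79 lower and 163 to 2069 at an unadjusted p under 0.05; the calls came from omitting the library labelled Ctrl 1 alone. With trimmed-mean scaling as well there were 517 (450 higher, 67 lower, 2093 unadjusted), without the libraries labelled Ctrl 1 and OE 3 1388 (964, 424, 2830), and with array weights 1394 (996, 398, 4044). Of the 597 genes, 512, 597 and 574 were called in these fits. Each fit leaves out the library labelled Ctrl 1 or gives it little weight, so this overlap is no independent support. The array weights were 0.41 for that library, 0.42 for OE 3, 5.82 for Ctrl 2 and 0.85 to 1.35 for the others. The 16 lists became 0 with an estimated correlation and 0 with fry. Apart from the omitted libraries, the cause of these changes was not tested.

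With the replicate number as a block, limma called 0 genes, 1797 at an unadjusted p under 0.05, and 16 lists; at the preset correlation the ATF4 list was lost and the megakaryocyte list gained. Same-numbered libraries deviated together with correlations of 0.44, 0.087 and 0.31, which does not settle whether the number marks a pair. OE 1 and the library labelled Ctrl 1, at 0.44, also share the listing of Col1a1 and Col1a2 at 0 and intermediate levels of Y-linked genes. OE 2 correlated best with the library labelled Ctrl 1 and OE 3 with Ctrl 2, a hint from the data against pairing by number.

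Mean log2 differences of lists that changed sign were, with a filter of 5 FPKM, −0.000995 for interferon and −0.077 for adipocytes; with scaling without marrow and muscle list genes, 0.034 for macrophages; without the libraries labelled Ctrl 1 and OE 3, 0.0075 for ATF4, −0.073 for interferon and −0.32 for marrow stroma; and with array weights, −0.073 for the respiratory chain, −0.11 for interferon and −0.19 for stroma. Over single omissions the ranges were -1.37 to 0.57 for erythroid cells, -1.16 to 0.016 for megakaryocytes, -0.13 to 0.030 for macrophages, -0.18 to 0.34 for adipocytes, -0.022 to 0.21 for endothelium, -0.033 to 0.32 for Schwann cells, -0.13 to 0.11 for the respiratory chain, -0.080 to 0.16 for interferon and -0.19 to 0.23 for stroma. For single genes they were -1.37 to 0.16 for Gata1, -0.57 to 0.21 for S100a8, -1.04 to 1.53 for Hbb-bs and -0.12 to 1.08 for Adipoq. Without the libraries labelled Ctrl 1 and OE 3, S100a8 was at 0.27 and Hbb-bs at −1.74; Hbb-bs was at −1.25 with array weights and −0.11 with trimmed-mean scaling without the library labelled Ctrl 1. Of the 38 sign changes 2 passed camera at the preset correlation and none with an estimated one, the adipocyte list without OE 3 and the respiratory chain list without Ctrl 3. The cause was not tested. Absolute depth is unknown, so its effect on Wnt7b and other genes near 1 FPKM was not measured.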

Other observations

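All tests in this part were chosen after the results they bear on were seen. Mitochondrially encoded genes, which form no list of the report, stood higher in each OE library than in each Ctrl library. The mean level of the 10 genes was 11.48, 11.09 and 11.23 in log2(FPKM + 1) in OE, 10.61 in the library labelled Ctrl 1, and 10.77 and 10.77 in Ctrl 2 and Ctrl 3. The difference was 0.55 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). All 10 had a positive difference, from 0.27 to 0.93, and 8 did not overlap between the groups, but none passed limma at an adjusted p of 0.05. mt-Nd3, a subunit of respiratory complex I, stood at 1835, 1744 and 1477 FPKM in OE, 1053 in the library labelled Ctrl 1, and 949 and 684 in Ctrl 2 and Ctrl 3. The difference was 0.60 with trimmed-mean scaling, where 8 genes did not overlap, and 0.64 with scaling without marrow and muscle list genes, where 5 did not. These genes are transcribed together and do not count as 10 separate measurements. In them the library labelled Ctrl 1 lay with Ctrl 2 and Ctrl 3, unlike in the bone lists.

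The library labelled Ctrl 1 lay with the OE libraries in bone genes. OE 1 and OE 2 both lay at least 1.33 in log2 above Ctrl 2 and Ctrl 3 in 4 bone lists. Exchanging either with the library labelled Ctrl 1 separated 1047 or 1361 genes, fewer than the 1651 of the labels. These values do not decide on such a swap. The gap counts against it only if a control must be low in bone genes, and the gene counts also follow differences in blood-cell content. A swap with OE 3 stays open too. That exchange separated 2891 genes, but it also groups the libraries by erythroid level, and OE 3 lay at least 1.07 above Ctrl 2 and Ctrl 3 in the bone lists. A candidate explanation is that Ctrl 2 and Ctrl 3 held less bone, cartilage and muscle tissue, although the labels describe all femurs as cleared of cartilage and marrow: 16 of 17 muscle genes were lower in both than in each other library, but the blood-cell lists did not differ alike between Ctrl 2 and Ctrl 3 and the libraries OE 1, OE 2, OE 3 and that labelled Ctrl 1, with levels of 6.54 and 5.98 against 4.04, 4.31, 7.93 and 4.12 for erythroid, 10.94 and 10.64 against 10.39, 10.84, 9.60 and 10.89 for neutrophil and 2.33 and 2.18 against 2.34, 2.85, 4.54 and 2.44 for B-cell genes. Megakaryocyte, T and NK cell and marrow stroma lists followed the erythroid list, higher in Ctrl 2, Ctrl 3 and OE 3 than elsewhere. T and NK cell levels were 2.38 and 2.29 against 1.67, 1.89, 2.44 and 1.84, in the same library order. Jchain, Iglc2, Cpa3 and Fcer1a, picked above as large decreases, were higher in Ctrl 2 and Ctrl 3 than in each other library. The blood-cell lists thus do not decide on this explanation. A single wrong label or an outside sample, which the count of 1651 does not decide, and an untested effect of Wnt7b on bone in the OE mice stay open too.

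Wnt7b was higher in the library labelled Ctrl 1 than in OE 2 and OE 3. Over OE 1, the library labelled Ctrl 1, OE 2 and OE 3, in falling order of Wnt7b, the same order held for 9 of 18 osteocyte genes, or 50%, against 7.14% of the 12177 genes tested and 0 of 17 muscle genes. The osteocyte genes move together (estimated correlation 0.59), so the 9 do not count as separate measurements. Ctrl 2 and Ctrl 3 were left out of this order. The shared order goes with the hypothesis that Wnt7b follows the bone-cell content of a library, but cannot decide on it. Whether Wnt7b in the library labelled Ctrl 1 came from the R26 allele or the Wnt7b locus cannot be told from FPKM per gene. A wrong label or a swap stays open here too.

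Y-linked genes stood at intermediate levels in OE 1 and the library labelled Ctrl 1. Ddx3y was at 3.42 FPKM in OE 1, 5.12 in the library labelled Ctrl 1 and 14.8 in OE 3, against 0.0183 in OE 2 and a listing at 0 in Ctrl 2 and Ctrl 3. Carry-over of the OE 3 library is argued against: Hbb-bs reached at most 2.85% of its OE 3 level in these libraries, while Ddx3y, Eif2s3y, Uty and Kdm5d reached 20.98% to 26.5% in OE 1 and 26.7% to 46.6% in the library labelled Ctrl 1. RNA of male and female mice may have been mixed in these libraries, since within each the 4 shares spread by at most 1.74-fold, and the labels give neither sex nor pooling. Y-linked levels were thus not balanced between the groups, and no biological explanation was tested.

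The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes at an adjusted p of 0.05 by limma, the real count was 0, which any split reaches. The highest other was 212, for OE 1, OE 2 and the library labelled Ctrl 1 against the rest, which points to a structure of the samples that the labels do not give. Erythroid levels divide the libraries in the same way, at 4.04, 4.31 and 4.12 against 7.93 in OE 3, 6.54 in Ctrl 2 and 5.98 in Ctrl 3, as do megakaryocyte levels. A swap of OE 3 with the library labelled Ctrl 1 would make the same split, so the count does not tell these apart. At an unadjusted p under 0.05, 4 of the 10 splits reached the real count of 999, and the highest other was 2264. For lists called by camera, 4 of the 10 reached 16, and the highest other was 18.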
